A study of Schizosaccharomyces pombe with 10 samples.

How the data were processed

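Chromatin immunoprecipitates (ChIP) of fission yeast were measured on Agilent 2-colour tiling arrays with 1 array per sample and 10 samples. H3K9me2 was measured in wt, dhp1-2, rrp6 deletion and rrp6 deletion dhp1-2 cells, and Red1-MYC, Mtl1-MYC and CFP-Mmi1 each in wt and dhp1-2 cells. Per the labels, cells grown at 30 °C were shifted to 37 °C for 5 h and fixed in 3% paraformaldehyde, those of Red1, Mtl1 and Mmi1 also with DMA for 45 min. Chromatin was sheared to 500 to 1000 bp. Cy5 carried the ChIP DNA and Cy3 the whole-cell extract DNA on every array. The H3K9me2 arrays of wt and dhp1-2 lie on one slide, those of the rrp6 deletion and the double mutant on another, the 4 of Red1 and Mtl1 on another and the 2 of Mmi1 on another.

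Per the file headers the scanner files were made with Agilent Feature Extraction 11.5.1.1 and hold 42968 features, of which 1417 are controls. The remaining 41551 probes were used, and 41251 of them lie on the 3 chromosomes with a step of 300 bp. The processed signals are, per the file headers, an intensity after background subtraction and dye normalization within the array. That step was a lowess on all arrays except those of the rrp6 deletion and the double mutant. The median and background-subtracted signals are, per the file headers, an intensity before dye normalization. The deposited value table holds for each array a ratio of Cy5 over Cy3. It was equal to the ratio of processed signals for 100% of probes, with medians of 0.94 to 0.99. The files name no genome build for their positions and none is given in the sources used here. Median Cy3 signals lay 44.6 to 149 times over their local background and median Cy5 signals 159 to 537 times. The software marked 27.7% of probes of the H3K9me2 wt array as uneven, 10.3% on the rrp6 deletion array and at most 3.02% on each of the others, and gave a failed grid flag to the wt array alone.

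Positions were matched to gene names by comparing the GC content of the reference sequence (assembly ASM294v3) with the Cy3 signal over shifts of up to 60 kb per chromosome arm. The 6 arms gave shifts of -880, 4360, -940, -1780, 40 and -950 bp with correlations of 0.41 to 0.43, against 0.04 to 0.08 for the next best shift. On simulated signals with known shifts the largest error was 10 bp. Shifts were used to say which gene and region a probe lies in and whether its window recurs in the genome. Printed positions of segments are those of the array files, while the region bounds below are positions of the reference. Probes whose window is made up of at least 50% recurring 60-mers were called repeated. Regions were fixed before the data were examined: pericentromeres at 3.75 to 3.792 Mb of chromosome I, 1.598 to 1.646 Mb of II and 1.068 to 1.14 Mb of III, the silent mating-type region at 2.11 to 2.14 Mb of II, subtelomeres as 50 kb at each end of I and II, and 25 kb at each end of III.

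The level of a probe was the log2 of processed Cy5 over processed Cy3 minus its median over all probes of the array. A gene's level was the mean over probes centred in it, for genes with at least 3 probes (7640 of 12645 annotated genes, 4620 of them protein-coding and 2992 long noncoding). Overlapping genes share probes, so counts of genes are not counts of separate loci. Spots marked by the software were kept, and leaving them out is an alternative. The 6 comparisons were dhp1-2 with wt for each of the 4 ChIP targets, rrp6 deletion with wt, and double mutant with rrp6 deletion. With 1 array per group no test has residual degrees of freedom, so no p-value was computed. A gene was counted as higher or lower at a log2 difference of 1 (2-fold) for H3K9me2 and of 0.585 (1.5-fold) for Red1, Mtl1 and Mmi1. Enriched segments were runs of at least 3 probes, at most 1500 bp apart, at or over the same values. The median of each of 13 fixed gene lists was placed among 10000 random lists matched in 10 bins of level, for lists of at least 5 measured genes. The bins hold equal numbers of genes, so the highest bin joins genes of moderate and of high level. Strongly enriched genes are thus matched only loosely, and a low percentile can follow in part from their high reference level. Of the list of Mmi1 targets mcp5 was not found by its symbol; the reference calls it num1, seen only after the values, so it is given apart from the list.

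Named genes are the 10 largest rises and 10 largest falls past the threshold with 1 gene per 2 kb, and the measured Mmi1 targets, phosphate genes, Tf2 elements and rrp6, by a rule written before the data were examined. Further genes (among them mae1, mae2, ura4, mmi1, nc-pho1 and the genes in long segments) were chosen after their values were seen. For Red1 the rule was applied a second time without the streak columns, also a choice made after the data were seen. Sense TNAAAC hexamers were counted per gene in the reference sequence.

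The count and segment steps were tested on simulated data built from the reference array of each comparison with all 7640 genes. In the simulation of H3K9me2 dhp1-2 against wt, 100% of 50 genes shifted down by 2 times the threshold and 90.0% of 50 genes shifted up by 1.25 times the threshold were called. None of 7259 unchanged genes was called, and 97 of 97 inserted segments were found. The noise was drawn for each probe on its own from a normal distribution, scaled to the median absolute deviation of the difference between the 2 arrays. It holds no streak, no outlying spots, no noise shared by neighbouring probes and no biological variation. The lack of calls among unchanged genes follows from this and gives no rate of false calls for the real arrays.

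Alternatives to the processing were normexp background correction (offset 50, limma 3.58.1 in R 4.3.3), no background correction, loess, the deposited ratios, centring on housekeeping and ribosomal protein genes, scaling by the median absolute deviation or to the pericentromeres, median per gene, 1 or 5 probes per gene, 500 bp flanks, leaving out marked or repeated probes, and other thresholds. The files hold no mean signals, so median signals stand in for them in the first 3. Background subtraction without dye normalization, leaving out the streak columns of the Red1 pair, and leaving out the segments at ura4 and rrp6, were added after the data were seen. The rest was computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The mitochondrial probes and those of separate mating-type and other contigs were left out of gene values.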

Results

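The label check came first. On the 2 arrays labelled rrp6 deletion the whole-cell extract signal over rrp6, the gene of a nuclear exosome subunit, differed from the median of the 10 arrays by -5.22 and -5.35 log2 units. On the other 8 arrays it lay between -0.11 and 0.15 of that median. The extract signals of red1, mtl1 and dhp1 lay within 0.1 of their medians on every array, and that of mmi1 was higher on the 2 Mmi1 arrays, by 0.39 and 0.53. Each genotype and ChIP target was measured on 1 array, so no difference below was tested or checked in a replicate. "Rose" and "fell" mean only that a gene's mean log2 ratio of ChIP over extract differed by at least 1 for H3K9me2, or by at least the log2 of 1.5 for Red1, Mtl1 and Mmi1.

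In dhp1-2 cells, which carry a mutant allele of the 5'-3' exonuclease gene dhp1, H3K9me2 was lower than in wt cells at the islands over meiotic genes. Over mei4, which encodes a meiotic forkhead transcription factor, it fell from 3.09 to 1.37, and over ssm4, a meiotic gene silenced in mitotic cells, from 3.38 to 1.42. Over mug9 it fell from 1.47 to 0.40, and over num1, also known as mcp5, the island went from 2.09 to 0.74. Over mcp7, a meiotic recombination gene, the level went from 2.88 to 2.07, which is under the threshold. The level over the acid phosphatase gene pho1 went from 1.05 to 0.15, also under the threshold. Of the 14 measured genes known as Mmi1 targets, 3 fell (mei4, ssm4 and mug9), none rose and 11 did neither. Their median difference was -0.18, at percentile 16.9 of 10000 random gene lists matched on level, which describes these arrays only.

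The marked chromosome regions were lower in dhp1-2 as well. The mean level of pericentromere I was 4.18 in wt and 3.01 in dhp1-2, that of pericentromere II 3.83 and 2.98, and that of pericentromere III 4.74 and 3.72. The silent mating-type region had 2.78 and 1.55, the subtelomeres of chromosome I 3.93 and 2.49, those of chromosome II 2.93 and 1.63, and the ends of chromosome III, beside the rDNA, 2.59 and 0.87. In log2 units these are differences of -1.17, -0.85, -1.02, -1.23, -1.44, -1.30 and -1.72. The ratio of the log2 means was 0.72 to 0.79 at the pericentromeres, 0.56 to 0.63 at the mating-type region and subtelomeres, and 0.34 at the ends of chromosome III. At the latter, before dye normalization, the ChIP signal alone went from 3.41 to 2.33 and the extract signal from -0.18 to 0.99, so the fall of the ratio comes from both. Without the scanner software's dye normalization the falls were larger, from -1.50 at pericentromere II to -2.27 at the ends of chromosome III. With loess normalization pericentromere III changed direction, to 0.18, and with the arrays scaled to the pericentromeres to 0.33.

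**Figure D1:**
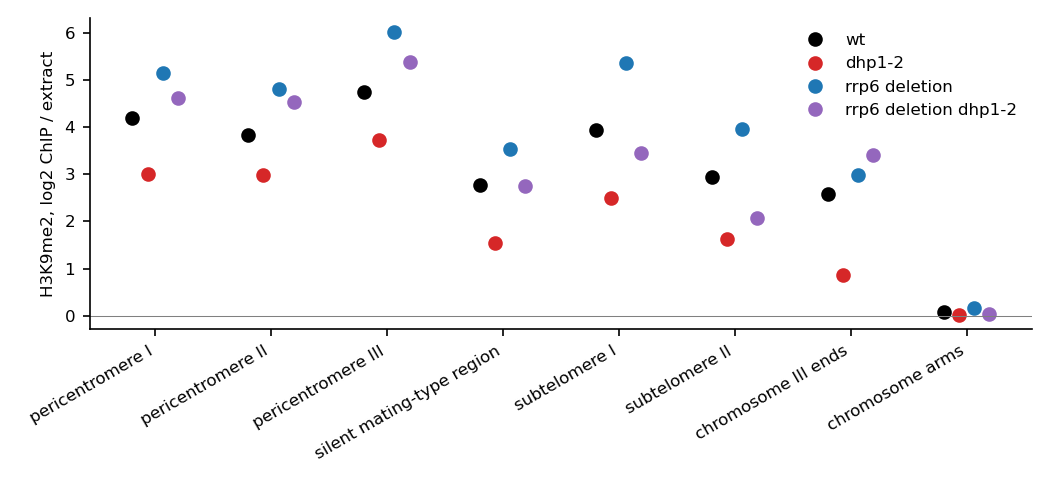
Mean H3K9me2 level (log2 ChIP over extract, centred on the array median) per region class on the 4 H3K9me2 arrays.

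The largest falls lay in few places. On chromosome III the fall was from 3.98 to -0.26 at SPCC569.01C, from 3.72 to -0.11 at SPCC569.03, and from 3.77 to 0.05 at the long noncoding RNA gene SPNCRNA.6679, and SPCP20C8.01C fell by 4.19 to -0.44. SPBC337.02C, on the arm of chromosome II, fell from 3.22 to -0.39. SPCC569.01C, SPCC569.03 and SPBC337.02C fell in the rrp6 deletion too, to 0.35, 0.43 and 0.30, so that among these 4 arrays the mark was high at them in wt alone. The next in rank were emc5 in pericentromere I (4.39 to 1.82), SPNCRNA.4502 (4.48 to 2.08) and SPAC977.04 (4.23 to 1.94) in the subtelomeres of chromosome I, and SPNCRNA.4520 (4.47 to 2.15) and SPNCRNA.448 (4.39 to 2.10) in those of chromosome II. All 5 probes of SPCC569.01C, and all those of SPCP20C8.01C, SPNCRNA.4520, SPNCRNA.448 and SPAC977.04, lie in sequence that recurs in the genome, so their signal is shared between copies.

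The wt array had 69 islands of H3K9me2 in the chromosome arms, which covered 283 kb. Their median level was 1.34 in wt and 0.61 in dhp1-2. 19 of them were lower by at least 1, none was higher by as much, and 58 lay below 1 in dhp1-2. These numbers include the island at ura4, whose extract signal was nearly absent on the wt array; without it 18 of 68 were lower and 57 lay below 1. The islands at mae1, the malate transporter gene (3.09 and 2.35), and at mae2, the malic enzyme gene (4.09 and 3.11), were the highest of the 69 islands in dhp1-2. Over mae2 the extract signal was low on both arrays, at -2.72 and -2.04 against the median of the 10 arrays, so these ratios rest partly on the extract. Islands flanking heterochromatin were lower too, such as the one at edc3 beside the mating-type region (1.63 and 0.46), the one at prp16 and cdc73 (1.44 and 0.38) and the one at any2 beside centromere I (1.48 and 0.62). Islands picked on the wt array are open to regression to the mean. No array was left over to value them on.

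Across the 7640 measured genes, 237 fell and 3 rose in dhp1-2. 118 of those that fell and none of those that rose code for protein, and 137 of those that fell lie in the chromosome arms. The highest rise was at SPNCRNA.1234, which overlaps the thiamine-regulated gene nmt1 (0.13 to 1.24, a difference of 1.11, or 1.57 with spots that the scanner software marked as uneven left out). The other 2 were SPNCRNA.7020 and SPNCRNA.3503, which overlap Tf2-12 and Tf2-4. Both had a difference of 1.08, which was 0.13 and 0.06 without dye normalization. The median of the 9 measured Tf2 retrotransposons went from -0.95 to -0.07, a difference of 0.91 with no member past the threshold, and of -0.03 without dye normalization. With loess normalization 72 genes rose and 287 fell, without dye normalization 8 and 459, and scaled to the pericentromeres 16 and 125. The 15 measured housekeeping genes had a median difference of -0.23, with 2 members lower, 13 that did neither and none higher.

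H3K9me2 was higher in the rrp6 deletion at many loci, most of which had little in wt. Over glm2 it rose from -0.02 to 5.11, and over the overlapping ste6, which encodes a Ras guanine nucleotide exchange factor, it reached 4.89. Over myp2, the gene of a myosin II heavy chain, it rose from -0.17 to 4.71, and over man1, the gene of an inner nuclear membrane protein, from -0.01 to 4.63. The phosphate genes gained the mark, with pho1, which lies in a wt island, going from 1.05 to 3.91, the phosphate transporter gene pho84 from 0.30 to 3.97 and the transporter gene tgp1 from 0.02 to 2.04. Over mcp3, a meiotic gene next to red1, it rose from 0.05 to 2.62. The Tf2 retrotransposons rose from a median of -0.95 to 3.80, with all 9 members past the threshold; the difference of 4.70 was 2.92 without dye normalization. Tf2-1, Tf2-9, Tf2-5 and Tf2-3 were among the 10 largest rises (4.94, 4.80, 4.70 and 4.70), with SPNCRNA.7020 over Tf2-12 (5.14), SPNCRNA.4345 over Tf2-8 (5.00) and SPNCRNA.3503 over Tf2-4 (4.87). At 3 probes of Tf2-4 that overlap SPNCRNA.3503, the rrp6 deletion extract signal was -1.66 against the median of the 10 arrays. The lowest other array had -0.28 there, so that rise rests partly on the extract. All probes of these elements lie in repeated sequence, so single copies were not told apart.

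Several other meiotic genes had less of the mark in the rrp6 deletion. The level over ssm4 fell from 3.38 to -0.08, over mei4 from 3.09 to 0.36, over mcp7 from 2.88 to -0.15 and over mug9 from 1.47 to -0.34. The overlapping noncoding genes SPNCRNA.4051 in ssm4 and SPNCRNA.5202 in mei4 fell by 3.67 and 3.11. SPCC70.08C fell from 2.10 to -0.33. The remaining large falls were those of SPCC569.01C (-3.63), SPCC569.03 (-3.29), SPBC337.02C (-2.92), SPNCRNA.6678 (-3.57), SPNCRNA.1297 (-1.76) and SPNCRNA.6680 (-1.46, but -0.92 and so under the threshold without dye normalization). The island at num1 was kept, with 2.09 and 1.38, and those at mae1 and mae2 had 3.47 and 4.70. Of the 14 measured Mmi1 targets, 1 rose (mcp3), 4 fell and 9 did neither, with a median difference of -0.33 (percentile 0.00). Other lists were low in this pair too. Housekeeping genes had -0.42 (percentile 0.00), heat shock genes -0.33 (percentile 0.12) and ribosomal protein genes -0.18 (percentile 0.22). The low percentile is thus not particular to the Mmi1 targets.

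Segments enriched in the rrp6 deletion that overlapped none of the wt array numbered 81 in the arms and covered 320 kb. Their median level was 0.10 in wt and 1.34 in the deletion. One of the 81 is rrp6 itself, which the strain lacks, so its value is not a gain of the mark. Of the other 80, 52 were higher than in wt by at least 1, and the rest differed by less and do not count as risen. The longest, 39.6 kb from position 5217600 to 5257199 of chromosome I, held smc5, mek1, man1, nab2, rad17 and atp1 and had a mean of 2.94. The next, 27.9 kb on chromosome III with ste6, glm2, rmr1, mme1, rpb3 and trp3, had 3.01. A segment of 17.4 kb around myp2 and lcb4 had 3.70, one of 17.1 kb with red1, mcp3, och1 and rgf2 had 2.15, and one of 12 kb with gpa2 and jmj1 had 1.85. One of 10.2 kb with tgp1 had 2.05. The wt island of 28.5 kb with fub2, nrg1 and say1 on chromosome II went from 1.70 to 4.59.

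Of the 7640 genes, 317 rose and 43 fell in the rrp6 deletion. Of those that rose, 232 lie in the chromosome arms, and 97 of the 317 lie mostly in repeated sequence. Those that rose include rrp6 and ura4, whose ratios rest on a nearly absent extract signal in the deletion and in wt respectively. With normexp background correction, 233 rose and 65 fell, and without dye normalization 217 rose and 47 fell. 28 of the 43 that fell also fell in dhp1-2; both comparisons use the same wt array. The constitutive heterochromatin was higher in the rrp6 deletion, by 0.97 at pericentromeres I and II, 1.27 at pericentromere III, 0.76 at the mating-type region, 1.43 at the subtelomeres of chromosome I and 1.02 at those of chromosome II. Without dye normalization these differences were 0.11, 0.08, 0.16, -0.33, 0.27 and 0.04. The 2 arrays lie on different slides that the software processed with different protocols, and only the wt array was dye-normalized by lowess, so no gain at constitutive heterochromatin can be read from them.

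**Figure D2:**
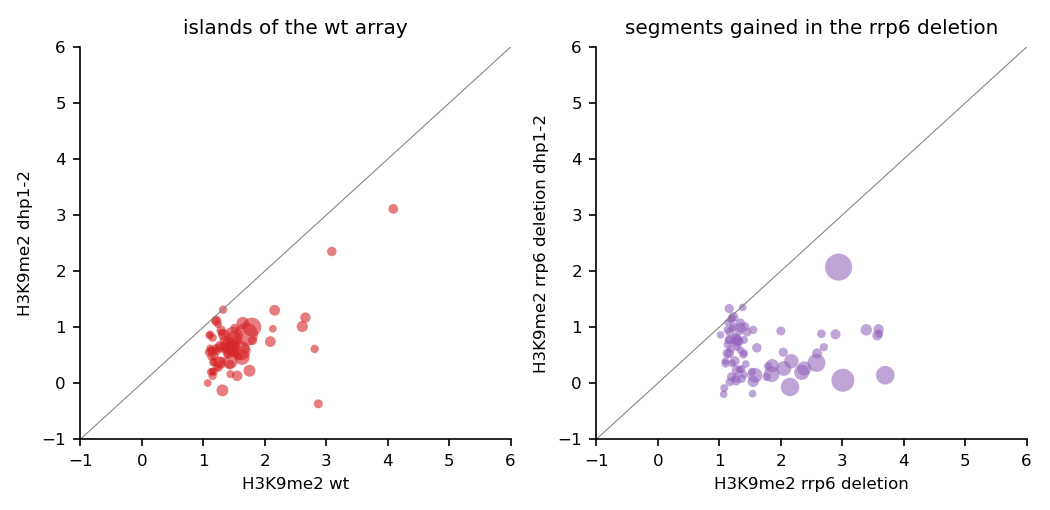
H3K9me2 of single segments. Left, islands of the wt array in wt and dhp1-2. Right, segments gained in the rrp6 deletion, in the deletion and the double mutant. Dot size follows segment length and the line marks equal levels.

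Most of the mark gained without rrp6 was missing when dhp1-2 was combined with the rrp6 deletion. Against the rrp6 deletion alone, the level over glm2 fell from 5.11 to 0.36, over ste6 from 4.89 to 0.24 and over myp2 from 4.71 to 0.33. It fell from 3.69 to 0.06 over lcb4 and from 4.22 to 0.26 over rmr1. At the cluster on the right arm of chromosome II it fell from 4.88 to 0.76 over SPNCRNA.6623 in say1, from 4.47 to 0.46 over nam3, from 4.60 to 0.95 over fub2, from 4.40 to 0.94 over SPNCRNA.6614 near ecl3 and by 3.41 from 4.41 over SPNCRNA.6627. The phosphate genes fell as a group: pho1 from 3.91 to 0.63, pho84 from 3.97 to 0.86 and tgp1 from 2.04 to 0.48. Over mcp3 it fell from 2.62 to -0.09, and the median of the Tf2 retrotransposons from 3.80 to 1.13 (9 of 9 lower). The largest fall of all, at ura4 (6.04 to 0.46), is not assigned to dhp1-2, because the ura4 genotypes of the strains are not given in the sources used here. The extract signal at ura4, at -1.06 and -0.80 against the median of the 10 arrays, was similar on these 2 arrays and does not account for it.

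The 81 gained segments went from a median of 1.34 to 0.63, with 38 lower by at least 1, none higher and 71 below 1 (37 and 70 of 80 without rrp6). Of the 52 that were higher than in wt by at least 1, 37 were lower in the double mutant and 49 lay below 1 there. Of the 13 that span at least 5 kb, 12 were lower by at least 1, and their median went from 2.34 to 0.26. The segment with ste6 and glm2 went from 3.01 to 0.05, that with myp2 from 3.70 to 0.14, that with red1 and mcp3 from 2.15 to -0.07, that with gpa2 from 1.85 to 0.16 and that with tgp1 from 2.05 to 0.26. The exception was the longest one, with man1 and atp1, at 2.94 and 2.07. The pericentromeres and the mating-type region changed less: pericentromeres I, II and III had 4.62, 4.53 and 5.37 in the double mutant, lower by 0.53, 0.28 and 0.64, and the mating-type region was lower by 0.78. The subtelomeres of chromosomes I and II were lower by 1.91 and 1.87. The ends of chromosome III were higher by 0.43. The islands at mae1 (3.47 and 3.06) and mae2 (4.70 and 4.21) were close to level in the 2 arrays, while that at num1 went from 1.38 to 0.07. Extract signals were low on these arrays at mae1 (-2.33 and -2.31) and mae2 (-2.75 and -2.62), so these ratios rest partly on the extract.

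Of the 7640 genes, 312 fell and none rose in the double mutant (276 and 30 with loess, 200 and 9 scaled to the pericentromeres); 167 of those that fell code for protein and 256 lie in the arms. Of the 317 genes that rose in the rrp6 deletion, those outside the arms included, 214 fell in the double mutant and 234 had a level within 1 of wt there. Genes picked for a high value on the rrp6 deletion array are expected to be lower on any other array by regression to the mean, and the correlation of -0.71 between the 2 sets of differences partly comes from the rrp6 deletion array that they share. 93 genes fell in dhp1-2 in both backgrounds, in pairs that share no array. Only genes with the mark in the reference array can fall by this much, so an overlap is to be expected and its size was not tested.

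In wt cells Red1 and Mtl1, 2 partners in a nuclear RNA elimination complex, shared many places. 136 of the 151 enriched Red1 segments overlapped a Mtl1 segment, and 132 of the 224 Mtl1 segments overlapped one of Red1. Both proteins carry a MYC tag and were measured on the same slide, and the samples hold no ChIP from untagged cells. Background common to both ChIPs was therefore not told apart from shared binding. 48 of the Red1 segments overlapped one of Mmi1, the YTH-family RNA-binding protein that recognizes meiotic transcripts. The highest Red1 levels of single genes were at SPNCRNA.1197 (3.10), SPNCRNA.5202 in mei4 (2.74), nc-pho1 (2.73), nc-tgp1 (2.57), mei4 (2.55) and pho1 (2.50). The highest of Mmi1 were at nam1 (2.61), SPNCRNA.3101 in mug8 (1.96), SPNCRNA.5202 (1.95), mei4 (1.74) and nc-tgp1 (1.73).

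In dhp1-2, 15 genes fell for Red1, Mtl1 and Mmi1 alike. Many of them overlap and share probes, so they are fewer loci than genes. At nc-tgp1, the long noncoding RNA gene upstream of tgp1, Red1 fell from 2.57 to 0.15, Mtl1 from 2.41 to 0.21 and Mmi1 from 1.73 to 0.04. At tgp1 itself the falls were from 1.54 to 0.30, from 1.55 to 0.34 and from 1.12 to 0.16, and SPNCRNA.4681, which spans both, fell by 2.00, 1.85 and 1.44. At mei4 Red1 fell from 2.55 to 1.28, Mtl1 from 2.78 to 1.19 and Mmi1 from 1.74 to 0.78. At ssm4 the falls were by 1.13, 0.94 and 0.76, at mcp7 from 2.05 to 0.65, from 2.05 to 0.73 and from 1.44 to 0.31, at mug8 by 0.78, 0.85 and 1.22, at num1 by 1.03, 1.01 and 1.01, at stb3 from 2.13 to 0.86, from 2.41 to 0.70 and from 1.26 to 0.26, and at nam1, a noncoding RNA gene over mlo3, by 0.68, 0.71 and 1.32. The other 5 were the noncoding genes SPNCRNA.3101 in mug8, SPNCRNA.6511 in stb3, SPNCRNA.5202 in mei4, SPNCRNA.4051 in ssm4 and SPNCRNA.1397 in num1. 7 of the 15 code for protein.

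**Figure D3:**
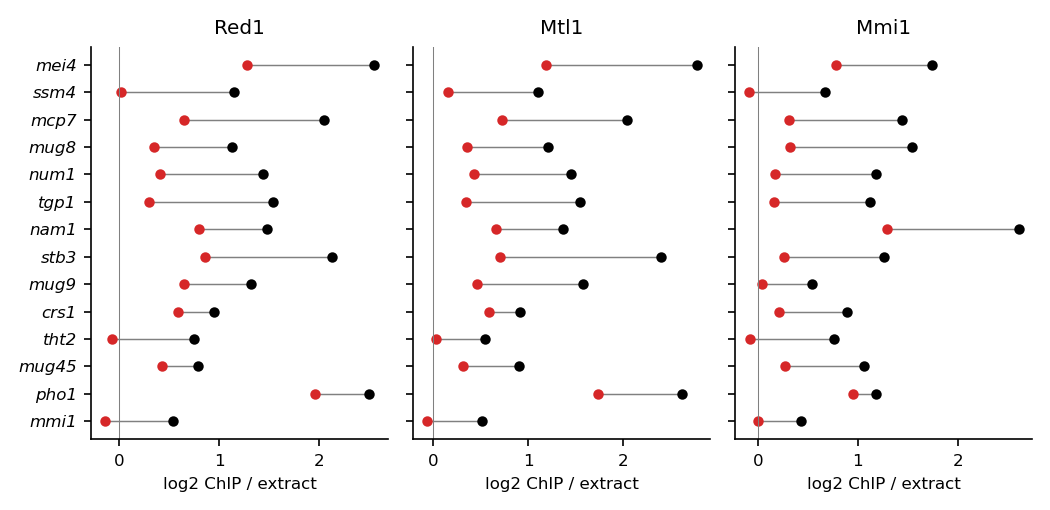
Level of Red1, Mtl1 and Mmi1 (log2 ChIP over extract) at named genes in wt (black) and dhp1-2 (red).

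For Red1, the 10 largest falls with the disturbed spots of this array pair left out included SPNCRNA.1197 (3.10 to 0.92), mbx2, a MADS-box transcription factor gene (2.07 to 0.22), SPNCRNA.1136 over ggc1 (2.25 to 0.50) and nam3 (0.89 to -0.26), with nc-tgp1, SPNCRNA.6511, SPNCRNA.4051, mcp7, SPNCRNA.5202 and num1. The 14 Mmi1 targets had a median difference of -0.47 (percentile 0.00), with 6 lower, none higher and 8 that did neither. The 150 wt segments in the arms went from a median of 0.79 to 0.72, with 20 lower and none higher, and 102 still overlapped an enriched segment in dhp1-2. These values hold all spots, those of the disturbed columns included, and the dhp1-2 array had more segments (229) than the wt array. pho1 had 2.50 and 1.96, under the threshold, and at the mmi1 gene Red1 fell by 0.68. The 56 ribosomal protein genes had a median of -0.17 (percentile 0.00), with 1 higher, none lower and 55 that did neither.

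The count of Red1 differences is limited by the array. 204 genes rose and 151 fell, but 28 rose and 42 fell when 10 of the 85 array columns, which form a streak on the dhp1-2 array, were left out. Leaving out the spots that the scanner software marked gave 47 and 42, centring on housekeeping and ribosomal protein genes 298 and 111, and loess 111 and 132. The 10 largest rises with all spots in, among them mrpl40 (4.22), SPNCRNA.4555 (3.48), SPNCRNA.1108 (3.39), SPNCRNA.5676 (3.37), SPNCRNA.6740 (3.31), SPNCRNA.2975 (3.28), SPNCRNA.4174 (3.12), ssu72 (2.99), SPNCRNA.910 (2.99) and tsr401 (2.68), had too few probes left or were gone once the streak was left out: SPNCRNA.6740 and tsr401, the only 2 with enough probes, had 0.15 and 0.19. The falls of SPNCRNA.4868, SPNCRNA.567, SPNCRNA.6839, SPNCRNA.2502, SPNCRNA.243 and SPNCRNA.3692 (by 1.99, 1.88, 1.84, 1.69, 1.66 and 1.62) had no probes to spare either. With the streak left out, the largest rises were at atl1 (1.33), SPAC1093.07 (1.21, but 0.06 without the marked spots), osr2 (1.05), SPNCRNA.396 (1.02), SPRRNA.48 (0.81), SPNCRNA.1237 over meu10 (0.79), SPNCRNA.6666 (0.77), aga1 (0.77), SPNCRNA.1695 over fub2 (0.72, but 0.57 without dye normalization) and SPRRNA.49 (0.71).

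Of the 59 genes at which Mtl1 fell in dhp1-2, 37 were among the 151 at which Red1 fell. Mtl1 fell by 2.28 from 3.35 at SPNCRNA.1197, from 2.51 to 0.46 at SPNCRNA.1136, from 2.16 to 0.24 at mbx2 and from 2.95 to 1.22 at SPNCRNA.5202 in mei4. It fell from 1.58 to 0.34 at SPNCRNA.6615 near pho84, and from 1.53 to 0.30 at SPNCRNA.5920 over rep1, a transcription activator gene of premeiotic growth. At pho1 it fell from 2.63 to 1.74. Of the 14 Mmi1 targets 6 fell, none rose and 8 did neither, with a median of -0.46 (percentile 0.00). The 223 wt segments in the arms went from a median of 0.81 to 0.57, with 26 lower and 1 higher, and 90 still overlapped an enriched segment in dhp1-2. The 56 ribosomal protein genes had a median of -0.33 and the 15 housekeeping genes one of -0.28 (both at percentile 0.00), with none past the threshold.

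Mtl1 rose at the rRNA genes SPRRNA.48 (-1.87 to -0.82), SPRRNA.49 (by 0.96, to -1.04), SPRRNA.47 (-1.84 to -1.01) and SPRRNA.42 (-1.64 to -0.89), and at SPNCRNA.3680 in pericentromere I (-2.81 to -1.80), where it was less depleted and not enriched. The other 5 largest rises were at SPNCRNA.7724 over inh1 (0.80), SPNCRNA.993 near mei2 (0.71), SPNCRNA.4477 over hry1 (0.66), sea4 (0.65) and SPNCRNA.4491 (0.64). Of the 7640 genes, 59 fell and 20 rose, and 12 of those that rose lie mostly in repeated sequence. Centred on the housekeeping and ribosomal protein genes, 33 fell and 155 rose.

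The largest falls of Mmi1 lay at meiotic and other genes. It fell from 1.96 to 0.32 at SPNCRNA.3101 in mug8, from 2.61 to 1.29 at nam1, by 1.20 to 0.30 at SPNCRNA.4831, from 1.42 to 0.26 at SPNCRNA.6511 in stb3, from 1.44 to 0.31 at mcp7 and from 1.56 to 0.65 at SPNCRNA.6222 over dbp2, an RNA helicase gene. Of the 14 Mmi1 targets 8 fell, none rose and 6 did neither, with a median of -0.65 (percentile 0.00). The level matching is loose for strongly enriched genes. Part of the low percentiles of this list for Red1, Mtl1 and Mmi1 can therefore follow from its wt enrichment. Of the wt segments in the arms, 35 of 83 were lower and none higher, the median went from 0.85 to 0.37, and 24 overlapped an enriched segment in dhp1-2. The segments of Red1, Mtl1 and Mmi1 were called on the wt array that gives their wt level, so part of these falls is expected from regression to the mean. At pho1 Mmi1 went from 1.18 to 0.95, under the threshold, and at the mmi1 gene it was lower by 0.43.

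Mmi1 rose at SPRRNA.48 (by 1.40), SPRRNA.49 (by 1.27), SPRRNA.47 (by 1.24) and SPRRNA.42 (by 1.06), again from levels under 0. It also rose at SPNCRNA.396 (by 1.22), and at SPNCRNA.3682 in pericentromere I (by 0.99). In the arms it rose at SPNCRNA.6621 over nrg1 (-0.76 to 0.25), SPNCRNA.1209 (-0.33 to 0.65), SPNCRNA.7703 over gst2 (-0.01 to 0.90) and omt3 (-0.37 to 0.50). Of the 7640 genes, 32 fell and 71 rose; centred on housekeeping and ribosomal protein genes, 21 fell and 197 rose. 19 genes fell for both Mtl1 and Mmi1. The median of the 56 ribosomal protein genes was -0.14 (percentile 0.00), with 1 lower, none higher and 55 that did neither.

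Along protein-coding genes of at least 1 kb, the wt Mmi1 level was highest in the 500 bp after the gene end (median 0.07) and in the 3' part (0.05), against -0.01 in the 5' part. In dhp1-2 these medians were 0.05, 0.02 and 0.01. Those of Red1 and Mtl1 lay between -0.03 and 0.03 in every part of the gene. The 14 measured Mmi1 targets carried a median of 6.48 sense TNAAAC hexamers per kb, the core of the Mmi1 recognition motif, against 1.66 in other protein-coding genes. These genes were listed as known Mmi1 targets, so a high density follows from the choice of the list. Across the 4620 protein-coding genes, hexamer density had a Spearman correlation of 0.13 with the wt Mmi1 level and of -0.08 with its dhp1-2 difference. With the wt levels of Red1, Mtl1 and H3K9me2 the correlations were -0.01, -0.05 and -0.01. With hexamers counted per gene instead of per kb, those of Mmi1 were 0.08 and -0.16, and those of the Red1, Mtl1 and H3K9me2 levels -0.14, -0.18 and -0.09.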

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

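The tests in this part were all chosen after the results they measure were seen. Differences between backgrounds were not tested, since each group holds 1 array.

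Values that differ in direction between backgrounds. At the ends of chromosome III, H3K9me2 was lower in dhp1-2 than in wt (-1.72) but higher in the double mutant than in the rrp6 deletion (0.43). At the Tf2 retrotransposons it went the other way, with 0.91 and -2.57. The first of these values rests in part on SPCC569.01C and SPCC569.03, which carried the mark on the wt array alone, and in part on an extract signal that was higher in dhp1-2 by 1.17, and the value of 0.91 was -0.03 without dye normalization. Neither difference was tested.

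Signals in the whole-cell extract channel, which no comparison uses on its own. Over ura4, a common marker gene, the extract signal relative to the median of the 10 arrays was -5.06 log2 units on the H3K9me2 wt array, -1.06 on the rrp6 deletion, -0.80 on the double mutant and -1.05 on the Mtl1 dhp1-2 array. Ratios over ura4 on the wt array are therefore not comparable with the others; the rrp6 deletion and double mutant extracts were similar there. At the ends of chromosome III, which hold rRNA genes, the extract signal was higher in dhp1-2 than in wt in all 4 pairs, by 1.17 (H3K9me2), 0.58 (Red1), 0.72 (Mtl1) and 0.61 (Mmi1), and lower by -0.10 in the double mutant than in the rrp6 deletion. No explanation for this was tested.

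Over the 339 probes of the pericentromeres the extract signal was low on the 4 H3K9me2 arrays, where the ChIP signal is high: -1.25 in wt, -0.87 in dhp1-2, -2.09 in the rrp6 deletion and -1.94 in the double mutant, relative to the array median. One explanation is that heterochromatin is poorly represented in every extract; against it, the lowest value among the 6 Red1, Mtl1 and Mmi1 arrays was 0.51. An interference between the 2 labelled DNAs on the array may be the cause: at 101 probes picked on Mtl1 for a loss in dhp1-2, the Red1 extract signal was lower in wt than in dhp1-2 by a median of -0.27, where the Red1 ChIP signal was higher by 0.93, against 0.01 at the other probes. On the Mmi1 pair, on another slide, these medians were -0.13 and 0.44 at the same probes. The pick and both readings compare wt with dhp1-2. A true difference between the extracts of the 2 genotypes at these loci could thus give such values too. A yield of heterochromatin in the extract that depends on the additional DMA fixation of the Red1, Mtl1 and Mmi1 samples stays open for the pericentromeres. With such an interference, ratios at strongly enriched loci would overstate the enrichment, though the pericentromere ChIP signal alone was high as well (3.96 in wt and 2.66 in dhp1-2).

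Genes higher for Red1 in dhp1-2. Of the 204 genes, 90.2% had a probe in the streak of 10 array columns, against 39.0% of measured genes. The streak is columns 43 to 52. They were picked because the Red1 difference had an SD there of over 2 times its median over columns. A lower count without them follows in part from that choice, and the other blocks were not picked in this way. With the streak columns left out 28 genes were past the threshold, while leaving out 7 other blocks of as many columns gave 198 to 207. Of the 204, 148 could still be measured and 26 of these were past it. A gain of Red1 shared with its partner Mtl1 would move Mtl1 too; the median Mtl1 difference of the 204 genes was 0.02 (standard error 0.02), so most of the rises are likely to come from the streak. For the 28 genes the Mtl1 median was 0.43, and a gain at some of them stays open.

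H3K9me2 at constitutive heterochromatin in the rrp6 deletion. Over 932 probes of the pericentromeres, the mating-type region and the subtelomeres the processed ratio was higher than in wt by 1.16 (SD over the 6 regions 0.24). The 2 slides were dye-normalized differently, and without that step the difference was 0.11 (SD 0.20). The rise may thus stem from the dye normalization. The ChIP signal alone differed by -0.45 (SD 0.37) and the extract signal by -0.49 (SD 0.37); as both were lower alike on the other slide, the ChIP signal alone does not decide on a gain of the mark, which stays open.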

How the results depend on the processing

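Alternatives were chosen before the data were examined, except background subtraction without dye normalization, leaving out the streak columns, and leaving out the ura4 island and rrp6 segment. No paired analysis was possible because each group holds 1 array, and leaving out a replicate was not possible for the same reason. All values here are counts or differences from no test; unless stated, the cause was not tested. The deposited ratios gave the values of the main processing by construction and say nothing on stability, so they are left out of the following numbers. Of the counts, 80 alternative values lay within 1.5 times the main one and 96 did not; of region differences 442 moved by less than their spread, 113 by more, and 5 of those past the threshold changed sign; of list medians 766 moved by less and 58 by more.

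Counts are given as higher and lower genes. For H3K9me2 dhp1-2 against wt (3 and 237) they were 31 and 454 with normexp, 5 and 458 without background correction, 8 and 459 without dye normalization, 16 and 125 scaled to pericentromeres, 29 and 483 with 1 probe, 1 and 111 with 5 probes, 6 and 463 with 500 bp flanks, 100 and 579 at 1.5-fold, and 0 and 53 at 3-fold. Higher genes alone went beyond 1.5 times with loess (72), housekeeping centring (17), medians per gene (8) and repeated probes left out (1). In every alternative more genes were lower than higher.

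For the rrp6 deletion against wt (317 and 43) they were 579 and 112 with 1 probe, 183 and 18 with 5 probes, 550 and 71 with flanks, 631 and 184 at 1.5-fold and 169 and 20 at 3-fold. Higher genes were 211 without background correction and 211 with repeated probes left out, and lower genes 65 with normexp and 28 with housekeeping centring. For the double mutant against the rrp6 deletion (0 and 312) they were 3 and 550 with 1 probe, 2 and 528 with flanks, 9 and 200 scaled to pericentromeres and 19 and 626 at 1.5-fold. Lower genes were 174 with 5 probes and 156 at 3-fold, and higher genes 8 with normexp, 30 with loess, 6 scaled by the median absolute deviation and 1 with medians per gene.

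For Red1 (204 and 151) they were 28 and 42 without the streak columns, 47 and 42 without marked spots, 39 and 44 with medians per gene, 102 and 98 with 5 probes, 322 and 232 with flanks, 88 and 64 at 2-fold and 32 and 12 at 3-fold; loess gave 111 higher and 1 probe 230 lower. For Mtl1 (20 and 59) they were 39 and 144 with normexp, 42 and 135 with loess, 155 and 33 with housekeeping centring, 42 and 93 with 1 probe, 7 and 37 with 5 probes, 2 and 24 at 2-fold and 0 and 9 at 3-fold; flanks gave 40 higher and leaving out repeated probes 8. For Mmi1 (71 and 32) they were 229 and 82 with normexp, 184 and 83 with loess, 197 and 21 with housekeeping centring, 137 and 61 with 1 probe, 7 and 11 at 2-fold and 0 and 2 at 3-fold; 5 probes gave 30 higher and flanks 58 lower. Fewer or more genes under other thresholds and probe minima follow from their construction. The change of Mtl1 from mostly lower to mostly higher follows from the centring genes, whose medians were -0.33 (ribosomal protein) and -0.28 (housekeeping).

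Islands of the wt array numbered 69, but 119 at 1.5-fold and 44 with runs of 5 probes, and segments gained in the rrp6 deletion 81, but 163 at 1.5-fold. At 1.5-fold, islands had a smaller median dhp1-2 difference of -0.54 (main -0.82) and gained segments a smaller median double mutant difference of -0.41 (main -0.87). Called on odd probes and valued on even ones, the islands had -0.76 and the gained segments -0.81. Odd and even probes share array and DNA fragments, so this takes out only the regression to the mean that comes from single-spot noise. Regression from noise that neighbouring probes or the whole array share stays in. Without the ura4 island the median was -0.82, and without the rrp6 segment -0.86.

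The 5 values past the threshold that changed sign were all region differences; smaller values could change sign too and are counted with the others. Pericentromere III in dhp1-2 against wt (-1.02) was 0.18 with loess and 0.33 scaled to pericentromeres, where the scaling takes out the common part by construction. In the rrp6 deletion against wt, pericentromere III (1.27) was -0.21 with normexp and -0.20 scaled by the median absolute deviation, and subtelomere II (1.02) was -0.15 with normexp. Among smaller values, in that pair the ends of chromosome III went from 0.39 to -0.66 and the mating-type region from 0.76 to -0.33 without dye normalization, and the Tf2 median of dhp1-2 against wt from 0.91 to -0.03. With Cy3 at 44.6 to 149 times background, signal over background limits few probes; the uneven spots of the wt, rrp6 deletion and Red1 arrays limit more.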

Other observations

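The test in this part was chosen after the values were seen. H3K9me2 over SPNCRNA.1234, which overlaps nmt1, was 0.13 in wt and 1.24 in dhp1-2, the highest rise of that pair, while nmt1 itself had 0.28 and 0.59; the thiamine content of the media is not given in the sources used here. The islands at mae1 and mae2 were present on all 4 H3K9me2 arrays, with 3.09, 2.35, 3.47 and 3.06 for mae1 and 4.09, 3.11, 4.70 and 4.21 for mae2. At mae2 they lay on low extract signals of -2.72, -2.04, -2.75 and -2.62. At 3 probes over mae1 the extract signal was low in the rrp6 deletion (-2.33) and the double mutant (-2.31). Red1, Mtl1 and Mmi1 levels in wt were 0.33, 0.37 and 0.12 at mae1 and -0.22, -0.34 and -0.09 at mae2. At the mmi1 gene Red1, Mtl1 and Mmi1 had 0.54, 0.51 and 0.43 in wt, all under the enrichment threshold, and -0.14, -0.07 and 0.00 in dhp1-2; only the Red1 difference passed the threshold.

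A domain at the right end of chromosome III was marked on the wt array, the only array with a failed grid flag. From the end inward, H3K9me2 in wt was 3.98 at SPCC569.01C, 3.72 at SPCC569.03, 1.75 in the island of SPCC569.06 and SPCC569.05C and 1.31 in that of SPCC569.07, SPCC569.09 and ade5. In the rrp6 deletion these islands had 0.25 and 0.11, and in the double mutant 0.03 and 0.03.

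The H3K9me2 loss at wt islands in dhp1-2 was set against a single lower ChIP efficiency of that array. Among the 8 islands with a wt level of at least 2, ura4 apart, a straight line of dhp1-2 level on wt level had a slope of 1.03 and a residual standard deviation of 0.86. That value came from SPBC337.02C: without it the standard deviation was 0.34, and without any other 1 island it was 0.87 to 0.94. mei4, ssm4, mcp7 with ubp8, num1, mae1, mae2 and the island at SPATRNAPHE.01 thus lay around one line with a standard deviation of 0.34. The slope of 1.03 is that of the fit with SPBC337.02C in. Falls were unequal, with gene differences of -1.72 over mei4 and -1.96 over ssm4 but -0.8 over mcp7. A common loss of the mark and a lower yield of the dhp1-2 ChIP could both give values around a line and cannot be told apart with 1 array. The same question was not tested for the double mutant. There the pericentromeres differed from the rrp6 deletion by -0.53, -0.28 and -0.64, the mating-type region by -0.78 and the subtelomeres of I and II by -1.91 and -1.87.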
